A study of Mus musculus with 15 samples.

How the data were processed

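Total RNA of 15 samples was measured on Illumina MouseRef-8 arrays with a biotin label. Per the labels and the design text, each replicate used its own virus stock, fibroblast preparation and transfection, and the 3 iPSC samples are independent clonal lines. The labels do not state whether the OSK control cultures received a control transfection. The deposited non-normalized table gives, per the file headers, a bead summary intensity for each probe and array, linear and without background subtraction, beside a detection p-value. The series table holds log2 values that the authors quantile normalized. They differed by at most 0.0279 from the logarithm of the intensities after quantile normalization, so no background had been subtracted in them. The submitters' processing notes name limma for those values, with no version.

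Intensities were background-corrected, quantile normalized and log2 transformed with neqc of limma 3.58.1 (R 4.3.3, offset 16), which took the background from the detection p-values. Probes with a detection p under 0.05 on at least 3 of the 15 arrays were kept, 14962 of 25697. Names came from the platform's probe table, which paired 23978 probes with 1 symbol each, 23962 of them through their gene ID, for 16593 genes, and 1719 probes stayed unnamed. Each gene was represented by its brightest kept probe, which left 10173 genes, and 878 kept probes without a name were tested by themselves in an alternative. Where a gene was undetected on all arrays of a group, a lower bound of its fold was computed against the lowest detected signal of each array.

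Groups followed the sample titles. In 3 samples of replicate 2 the treatment tag conflicts with the title: the sample titled miR-181 has no treatment, the one titled miR-294 is tagged miR-181, and the one titled uninfected fibroblasts is tagged miR-294. Read in the order of the sample numbers, these tags sit 1 sample late. Groups from the tags and a fit without these 3 arrays were run as alternatives. In the groups from the tags, the array titled uninfected fibroblasts was left out rather than counted as miR-294, so the groups differed in size.

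All 15 arrays entered 1 limma fit with 5 group means, with 10 residual degrees of freedom and 3.19 prior ones, and 5 comparisons were drawn from it. P-values were two-sided and adjusted by Benjamini-Hochberg over the 10173 genes of each comparison, with a threshold of 0.05. The groups, the test, the comparisons, 28 gene lists and the rule for named genes were fixed before the data were examined. Pairing by replicate number was checked once. After removal of group means, day 3 arrays of the same number correlated at 0.209 to 0.682 in all 18 pairs, iPSC with day 3 arrays of their number at 0.154 to 0.505, and arrays of different numbers at a median of -0.307. Among the latter, pairs of replicate 1 with replicate 2 or 3 were negative, and pairs of replicates 2 and 3 were positive, at 0.0985 to 0.419. Of the 15 arrays, 13 correlated best with their own number. The pattern thus mainly set replicate 1 apart, and pairing of numbers 2 and 3 was less clear. The labels say that each replicate had its own materials but not that a number was shared between groups, so the fit held no block. Before normalization the median signal of an array was 131.9 to 138.8 in replicate 1, 166.7 to 172.7 in replicate 2 and 155.4 to 161.0 in replicate 3. The number thus marks a difference between arrays in every group, iPSC included, which the labels do not name. Blocked values are given for the counts of changed genes, for list calls that changed and for the members of some lists.

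The lists were reprogramming factors, pluripotency, epithelial, mesenchymal regulators, fibroblast matrix, TGF-beta response, p53 targets, G1/S, G2/M, interferon response, inflammatory cytokines, Wnt targets, Akt and growth factor signalling, glycolysis, chromatin regulators, early lineage, Hox, imprinted, sex-linked, macrophage, endothelial, muscle, neural and adipocyte genes. Reported targets of each microRNA from other studies and targets that this study is known to have followed made 4 further lists, recalled from general knowledge. The sex-linked list, with 2 measured members, was under the minimum of 3 and was not tested as a list, so 27 lists were. Lists share members, such as the 3 factors in pluripotency. Each list was compared with all other genes by camera with a preset correlation of 0.01, adjusted over the 27 lists, with an estimated correlation and with fry, which asks if a list's genes move one way on balance. Sets of 200 genes highest in iPSC or in fibroblasts were tested the same way in the microRNA comparisons, whose arrays they do not share, adjusted over the 4 tests.

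Named genes were the 6 highest and 6 lowest fold changes among genes past the threshold whose arrays did not overlap, up to 4 members of each list with the smallest p, and the factor and target lists. Not all of them are printed. Transcripts with a predicted name were passed over. L1td1 and the 8 genes raised by both microRNAs were named after their values were seen.

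The steps were tested on simulated data built like the miR-294 comparison, with 200 of 10173 genes changed in each of 20 draws. Of genes changed by a log2 fold of 0.5, 24.9% were recovered, 72.8% at 1 and 95.8% at 2, and 4.84% of the calls were false. The simulated errors were independent between genes and arrays, without the deviations that real arrays of a number share. These rates therefore check the steps under that model and need not hold for the real arrays. The number of arrays limits the precision, and the median standard error of a log2 fold change was 0.173.

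Alternatives changed the background correction, the scaling, the detection filter, the probe choice, the arrays in the fit, the replicate block, the variance moderation, array weights, a minimum fold, the labels and the set test, and left out each array in turn. Tests of microRNA seed sites were not run, since no transcript sequences were used here, and a block for the BeadChip was not run, since its number is not given in the sources used here. Figures were drawn with matplotlib 3.10.9.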

Results

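Gene expression was measured on 15 BeadChip arrays of mouse cells that carried an Oct4-GFP transgene, in 5 groups of 3 arrays each. Uninfected embryonic fibroblasts (MEF), fibroblasts infected with virus for Oct4, Sox2 and Klf4 (OSK control), and OSK-infected fibroblasts given the microRNA miR-294 or miR-181 were collected at day 3. The fifth group held 3 clonal lines of induced pluripotent stem cells (iPSC). Each array detected between 11969 and 13377 of its 25697 probes, or 46.6% to 52.1%, and 10173 named genes were tested. Correlations across genes between arrays of a group were 0.975 to 0.995. The first principal component held 77.4% of the variance and separated the iPSC arrays from the day 3 arrays, and the third, with 5.97%, separated the replicate 1 arrays of every group from replicates 2 and 3. Log2 fold changes are given with their standard error (±), n = 3 arrays per group, and a gene or list rose or fell only where its adjusted p in limma passed 0.05. That error pools the spread within all 5 groups, also for comparisons at day 3. The median SD of a gene was 0.215 in iPSC and 0.154 to 0.173 in the day 3 groups.

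At day 3 the transcripts of all 3 delivered factors were higher in OSK control cultures than in uninfected fibroblasts. This comparison asks what OSK infection had done by then. It cannot part the factors from viral infection itself, since no group received virus without them. Nor can it part them from a control transfection, which the labels neither state nor exclude. Sox2 was at least 72.5-fold higher (adjusted p = 3.75e-11), Pou5f1, which encodes Oct4, rose by 4.99 ± 0.36 (adjusted p = 5.62e-07), and Klf4 rose by 2.74 ± 0.30 (adjusted p = 3.41e-05). The cell-cycle lists fell at the same time, and the pluripotency, epithelial and fibroblast matrix lists did not shift. Of the 10173 genes, 1006 changed, 592 of them upward and 414 downward, and 314 changed at least 2-fold. Under median scaling 430 were higher and 442 lower, and 665 changed without OSK control array 3 and 602 without the 3 arrays whose treatment tags conflict with their titles. A second Sox2 probe was detected on the iPSC arrays only, at a mean log2 signal of 5.61 (SD 0.59), and 1 of the 3 Klf4 probes averaged 6.93 in fibroblasts and 7.67 in OSK control cultures.

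**Figure D1:**
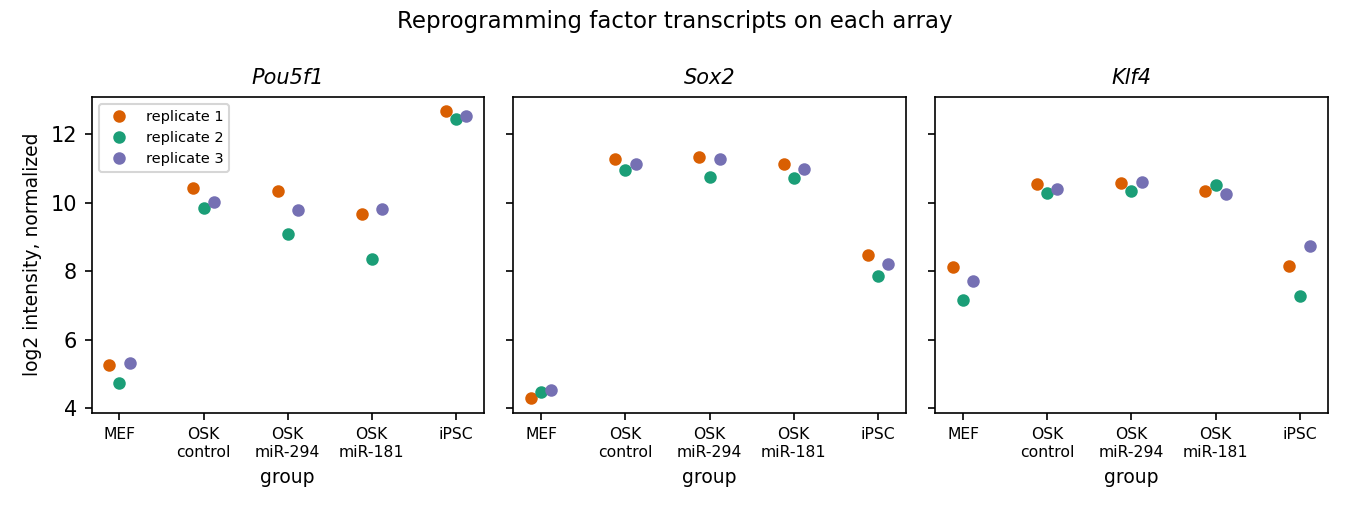
Normalized log2 intensity of the tested Pou5f1, Sox2 and Klf4 probes (vertical axes) on each of the 15 arrays by group (horizontal axes), coloured by replicate number. Mean Sox2 signal was 4.43 in fibroblasts, 11.12 in OSK control cultures and 8.19 in iPSC, and mean Klf4 signal was 7.67, 10.41 and 8.05.

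Among the genes with the highest fold changes after OSK infection, Pmch, the precursor of a neuropeptide, was at least 115-fold higher, the steroid dehydrogenase gene Akr1c18 at least 59.0-fold and the thyroid hormone-binding Crym at least 46.0-fold. Igfbp3, a carrier of insulin-like growth factors, rose by 6.25 ± 0.23 and Scg5, a chaperone of secretory granules, by 5.46 ± 0.20. The largest decrease was in the chemokine gene Cxcl12, which fell by 2.66 (SE 0.42, adjusted p = 0.000787). Slco4a1, an organic anion transporter, was at least 3.09-fold lower. Smoc1, Cx3cl1 and the collagen gene Col10a1 changed by -1.71 ± 0.20, -1.66 ± 0.19 and -1.65 ± 0.19.

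The G2/M list fell, with 10 of its 20 measured members lower and a median of -0.45. Cdc20 and Bub1b, regulators of the anaphase-promoting complex, changed by -0.62 ± 0.10 and -0.70 ± 0.13, and the cytokinesis genes Prc1 and Kif23 by -0.62 ± 0.11 and -0.71 ± 0.14. The G1/S list fell as well, with 7 of 29 lower and a median of -0.32, among them the replication licensing genes Mcm2 (-0.73 ± 0.16) and Cdt1 (-0.69 ± 0.13) and the uracil glycosylase gene Ung (-0.71 ± 0.10). Adjusted over the list alone, 14 G2/M and 10 G1/S genes were lower. Of 28 chromatin regulators 3 fell, Smarcd3 (-0.72 ± 0.18), the DNA methyltransferase Dnmt3b (-0.61 ± 0.16) and the histone chaperone subunit Chaf1b (-0.42 ± 0.12), and the list's median was -0.21. Adjusted camera p-values were 1.26e-07 for G2/M, 0.00235 for G1/S and 0.0199 for chromatin regulators, and 0.0496 for each with an estimated correlation.

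Of 33 pluripotency genes, 4 rose after OSK infection and 2 fell. The 4 were the 3 factors themselves and L1td1, and the 2 were Dnmt3b and Mybl2 (-0.62 ± 0.15), a cell-cycle transcription factor. Among 25 epithelial genes 0 rose and 4 fell, the cadherin gene Cdh3 (-1.19 ± 0.11), Cldn4 (-1.44 ± 0.20), Krt7 (-1.42 ± 0.21) and Krt18 (-1.33 ± 0.32). In the fibroblast matrix list Dcn, encoding decorin, rose by 3.34 ± 0.39, Pdgfra changed by -0.53 ± 0.13, the elastin gene Eln fell, and 21 of 24 did not pass. Of 13 mesenchymal regulators, Meox2 was at least 3.17-fold higher and Snai1, a repressor of E-cadherin, changed by -0.82 ± 0.22. Of 25 TGF-beta response genes 2 rose, Tgfbi (1.06 ± 0.15) and Tgfbr1 (0.39 ± 0.10). Camera's adjusted p was 0.755 for the pluripotency, mesenchymal, fibroblast matrix and TGF-beta lists and 0.394 for the epithelial list, and fry gave 0.00189 for the pluripotency and 0.023 for the epithelial list. Median, mean and test differed in sign for these lists except the mesenchymal one, and for the cytokine, glycolysis, Hox, macrophage and endothelial lists and the miR-181 targets from other studies.

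Some genes of the signalling and lineage lists changed after OSK infection. Among Wnt targets, Wnt4 rose by 1.22 ± 0.19 and Axin2, a feedback inhibitor of the pathway, was at least 2.38-fold higher, with 3 of 17 higher in all (adjusted p = 0.196). The growth factor gene Igf1 rose by 3.56 ± 0.19, with 3 of 23 Akt and growth factor genes higher (adjusted p = 0.313), and the glucose transporter gene Slc2a3 by 2.22 ± 0.21, with 2 of 18 glycolysis genes higher (adjusted p = 0.538). Il1rn, the interleukin 1 receptor antagonist, was at least 8.56-fold higher, the 1 of 20 cytokine genes that passed, where 5 were higher and 3 lower with replicate blocks. Markers of other cell types included the macrophage gene Laptm5 (3.55 ± 0.23, 1 of 8 higher), the endothelial receptor Tek (at least 7.68-fold, 1 of 11 higher and 1 lower), the muscle regulator Mef2c (1.73 ± 0.14, 1 of 8), the adipocyte gene Lpl (0.77 ± 0.19, 1 of 3) and the neural genes Stmn2 (1.82 ± 0.17) and Nefm (at least 2.63-fold). The neural list shifted upward at a median of 0.35, with 2 of 7 higher (adjusted p = 0.0451), and its adjusted p was 0.117 with an estimated correlation, 0.0517 with offset 50, 0.058 in the authors' values and 0.0631 on the 12 day 3 arrays without a block. The macrophage, endothelial, muscle, adipocyte and cytokine lists did not shift (adjusted p = 0.755, 0.843, 0.39, 0.755 and 0.755). Among p53 targets Fas rose by 0.97 ± 0.25 and Epha2 changed by -0.49 ± 0.13, of 25 measured (list adjusted p = 0.755). The target lists of the microRNAs did not shift, with adjusted p of 0.755 and 0.184 for miR-294 and 0.843 and 0.755 for miR-181. None of 23 interferon response, 10 early lineage, 25 Hox or 16 imprinted genes passed limma's test, which gave an unadjusted p under 0.05 for 2259 of all genes. Their lists did not shift in camera (adjusted p = 0.755, 0.755, 0.843 and 0.475), and fry gave these 4 adjusted p-values of 0.589, 0.391, 0.887 and 0.17. Fry called 11 of the 27 lists, among them the Wnt (adjusted p = 0.00448), Akt (0.0151), endothelial (0.00736) and muscle lists (0.00245).

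The arrays of the groups did not overlap for 1003 of the 1006 genes, where chance separates 10% of all genes, against 31.1% observed among all genes. With the replicate number as a block over the 12 day 3 arrays, 2088 genes changed, and on replicates 2 and 3 alone 772. With that block 1 G1/S gene was higher and 11 lower, 6 chromatin regulators were lower, and 4 glycolysis genes and 3 interferon response genes were higher. Higher and lower were 4 and 6 fibroblast matrix genes, 5 and 4 TGF-beta response genes, 2 and 2 mesenchymal regulators, 5 and 2 Akt genes, 4 and 2 Wnt targets, 1 and 3 p53 targets, 1 and 2 Hox genes and 1 and 3 imprinted genes. Pluripotency genes were 4 and 4, G2/M genes 0 and 13, and neural markers 3 and 1. Endothelial markers were 1 and 2, muscle markers 1 and 1 and adipocyte markers 1 and 1. Targets from other studies were 2 and 2 for miR-294 and 2 and 3 for miR-181, and 1 miR-294 target followed by this study was higher.

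Cell-cycle genes were higher in OSK-infected cultures given miR-294 than in OSK control cultures, the comparison that asks what this microRNA, of a family abundant in embryonic stem cells, added to the factors. Of 20 G2/M genes 10 rose and 0 fell, at a median of 0.62. Cdc20 rose by 0.96 ± 0.10 (adjusted p = 0.000601), the mitotic kinase gene Aurka by 0.87 ± 0.12 (adjusted p = 0.00442), Plk1 by 0.75 ± 0.12 and Cdk1, the main mitotic kinase, by 0.70 ± 0.11. Of 29 G1/S genes 5 rose, including Ung (0.74 ± 0.10), Mcm5 (0.81 ± 0.13) and Mcm4 (0.42 ± 0.09), and 1 fell, the transcription factor E2f1 (-0.49 ± 0.11), at a list median of 0.37. In all 201 genes changed, 151 higher and 50 lower, and 28 changed at least 2-fold.

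Adjusted over the list alone, 16 G2/M genes and 13 G1/S genes were higher and 1 G1/S gene was lower. Camera's adjusted p was 1.89e-19 for G2/M and 2.19e-07 for G1/S, and 0.00314 and 0.00508 with an estimated correlation. Chromatin regulators rose as a list at a median of 0.12 (adjusted p = 0.00155, and 0.0178 with an estimated correlation), with 3 of 28 higher, Dnmt3b (0.86 ± 0.16), the damage-marked histone gene H2ax (0.54 ± 0.11) and Parp1 (0.45 ± 0.11). Set against the mean of the control arrays, the G2/M median was 0.56 to 0.67 on the miR-294 arrays, 0.38 to 0.56 on the miR-181 arrays and 0.47 to 0.62 on the uninfected fibroblast arrays. Against fibroblasts, the G2/M median was 0.151 with miR-294 and -0.0706 with miR-181, and these comparisons were not tested.

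**Figure D2:**
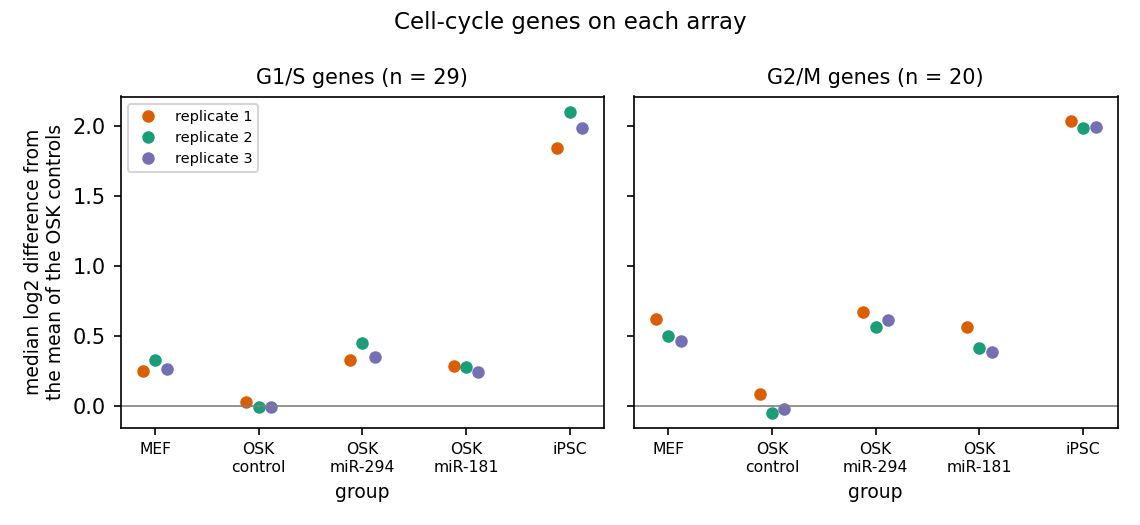
Median log2 level of the G1/S and G2/M lists on each array (vertical axes), relative to the mean of the 3 OSK control arrays, by group (horizontal axes) and coloured by replicate number. OSK control arrays lay between -0.05 and 0.09 for G2/M, all other day 3 arrays at 0.38 or above and iPSC arrays at 1.99 or above.

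Outside the 2 cell-cycle lists, genes among the highest fold changes with miR-294 were the repressor gene Msc (1.53 ± 0.27, adjusted p = 0.0129), the proton pump gene Atp12a (1.48 ± 0.24), the pentraxin Ptx3 (1.43 ± 0.34, adjusted p = 0.0497, and 0.0674 on the 12 day 3 arrays without a block), the keratin gene Krt8 (1.38 ± 0.25) and Cdkn1c (1.38 ± 0.23). Cdkn1c, an inhibitor of cyclin-dependent kinases, was also the 1 of 16 imprinted genes that rose (list adjusted p = 0.249), and Krt8 the 1 of 25 epithelial genes (0.112). The lowest were Rpia, an enzyme of the pentose phosphate pathway (-1.09 ± 0.17, adjusted p = 0.0075), Akr1c19 (-1.01 ± 0.13), the deubiquitinase Uchl1 (-0.95 ± 0.13), the histone gene H2bc6 (-0.95 ± 0.19), Os9 (-0.93 ± 0.12) and the actin-severing cofilin Cfl2 (-0.92 ± 0.20, adjusted p = 0.0301).

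Cfl2 was the 1 gene that fell among 6 measured targets followed by this study, a list chosen partly on these arrays and so not independent evidence. Its median was -0.40 (adjusted p = 4.04e-05, and 0.0654 with an estimated correlation), and 4 members were lower adjusted over the list alone. Among 12 targets of the miR-294 family taken from other studies 0 passed and the median was -0.19, with 1 higher and 2 lower adjusted over the list alone. For that list the adjusted camera p was 0.0734, fry gave 0.00536, the 12 day 3 arrays 0.0311 without a block and 0.00676 with it, the authors' values 0.0318, and an estimated correlation 0.134. Both lists hold Tgfbr2 (-0.82 ± 0.25, adjusted p = 0.134, and 0.00288 without and 0.00162 with the block on the 12 day 3 arrays) and Cdkn1a (-0.44 ± 0.12, adjusted p = 0.0766, 0.0283 without and 0.0222 with it), which encodes the kinase inhibitor p21. Targets of miR-181 had medians of 0.13 for 19 genes from other studies and 0.11 for 4 followed by this study, with 0 past the test in each (adjusted p = 0.158 and 0.983).

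The 3 factor transcripts did not pass the test with miR-294. Sox2 averaged 11.12 in both groups, and the list's adjusted p was 0.855. Of 33 pluripotency genes 2 rose, Mybl2 (0.86 ± 0.15) and Dnmt3b, at a list median of 0.06 (adjusted p = 0.118), and 6 rose adjusted over the list alone. Of 25 p53 targets 4 rose, including Apaf1 (0.66 ± 0.11), Trp53inp1 (0.67 ± 0.14) and Mdm2 (0.44 ± 0.09), and 1 fell, Rrm2b (-0.60 ± 0.13), and the list did not shift (adjusted p = 0.158). In the TGF-beta list Tgfbi (0.71 ± 0.15) and Smad6 (0.50 ± 0.11) rose (list adjusted p = 0.87), and Icam1 rose among the cytokine genes (1.01 ± 0.16, 0.983) and Slc2a3 among the glycolysis genes (1.33 ± 0.21, 0.597). None of 13 mesenchymal regulators or 24 fibroblast matrix genes passed, and their list adjusted p-values were 0.307 and 0.744. The interferon, Wnt, Akt, early lineage, Hox, neural and adipocyte lists also held 0 genes that passed, with adjusted p-values of 0.664, 0.855, 0.865, 0.306, 0.719, 0.865 and 0.249. Limma's unadjusted p was under 0.05 for 1244 genes in all, and fry called 9 of the 27 lists, including the pluripotency list (adjusted p = 0.0344), the epithelial list (0.0491) and the p53 list (0.0131). For the factors, the cytokines and the miR-181 targets followed by this study, median, mean and test differed in sign.

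Markers of other cell types that rose with miR-294 were Laptm5 (1.31 ± 0.23, 1 of 8 macrophage markers, list adjusted p = 0.855), Tek (0.78 ± 0.13, 1 of 11 endothelial markers) and the cardiac actin gene Actc1 (at least 1.96-fold, 1 of 8 muscle markers, 0.633). The endothelial list shifted upward at a median of 0.19 (adjusted p = 0.037), or 0.0954 with an estimated correlation, 0.0542 with offset 50 and 0.0617 under median scaling. Its median was 0.0140 when members undetected in a group were set at their bound.

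Arrays did not overlap for any of the 201 genes, nor for 21.5% of all genes, where chance gives 10%. Passing the threshold makes this likely by itself. With replicate blocks 13 G1/S genes were higher and 2 lower, 15 G2/M genes were higher, 5 pluripotency genes were higher and 3 miR-294 targets of each list were lower. Of the other lists with 0 genes past the test, the block gave 2 early lineage, 1 Hox, 1 Akt and 1 neural gene and 1 miR-181 target from other studies higher. It gave 2 mesenchymal regulators, 1 fibroblast matrix gene and 1 Wnt target lower. The count was 713 with replicate blocks, 31 on replicates 2 and 3 alone and 33 to 102 with any 1 of the 6 arrays left out. It was 72 under median scaling, 339 in the authors' values, 327 on the 12 day 3 arrays without a block, 16 without the 3 arrays with conflicting tags and 1 with groups from the tags.

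The same cell-cycle lists rose with miR-181, the comparison that asks what this microRNA added to the factors. Against OSK control cultures 23 genes changed, 20 higher and 3 lower, and 7 changed at least 2-fold. The G2/M list rose at a median of 0.44 with Cdc20 (0.53 ± 0.10, adjusted p = 0.0482) the 1 member of 20 past the test, and the G1/S list at 0.25 with 0 of 29 past it. Adjusted over the list alone, 14 G2/M and 8 G1/S genes were higher. Camera's adjusted p was 8.25e-16 for G2/M and 3.16e-10 for G1/S, and 0.00358 and 0.00271 with an estimated correlation. Chromatin regulators rose as a list at a median of 0.16, with H2ax (0.74 ± 0.11) the 1 of 28 past the test (adjusted p = 0.00018, and 0.00644 with an estimated correlation).

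The highest fold change with miR-181 was in Fbp2, a muscle fructose bisphosphatase of gluconeogenesis (1.73 ± 0.19, adjusted p = 0.00662). Atp12a rose by 1.52 ± 0.24, the protocadherin gene Pcdh17 by 1.21 ± 0.21, the G protein subunit gene Gna14 by 1.12 ± 0.14 and the adaptor gene Dok2 by 1.04 ± 0.16, and the glutathione transferase gene Gsta3 was at least 1.77-fold higher. The 3 genes that fell were Emc2, of the endoplasmic reticulum membrane complex (-0.68 ± 0.10, adjusted p = 0.0161), Lyrm1 (-0.67 ± 0.12) and Col18a1, whose product yields endostatin (-0.63 ± 0.11).

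Among 19 targets of the miR-181 family from other studies 0 passed and the median was 0.02 (adjusted p = 0.978), and camera's direction for that list was down. Among 4 targets followed by this study, a list that is not independent evidence, 0 passed and the median was -0.09 (adjusted p = 0.305). Bcl2 stood at -0.24 ± 0.14 and Cpsf6 at -0.43 ± 0.22. Timp3 stood at -0.44 ± 0.46 (adjusted p = 0.97, and 0.0946 without and 0.0396 with a block on the 12 day 3 arrays). The miR-294 targets had adjusted p-values of 0.717 for those from other studies and 0.181 for those followed by this study, at medians of 0.13 and -0.09. The other 20 lists held 0 genes that passed and did not shift. They included pluripotency (median 0.06, adjusted p = 0.924), mesenchymal regulators (-0.04, 0.861), fibroblast matrix (-0.10, 0.157) and the TGF-beta response (-0.10, 0.203). On the 12 day 3 arrays the fibroblast matrix and TGF-beta lists had adjusted p-values of 0.00027 and 0.0256 without a block and 0.00233 and 0.031 with it. The fibroblast matrix list had 0.0482 in the authors' values and 0.0166 under median scaling, and fry called the 3 cell-cycle and chromatin lists only. Limma's unadjusted p was under 0.05 for 831 genes. Signs of median, mean and test differed for the Akt, early lineage, Hox, macrophage and muscle lists and the miR-181 targets from other studies.

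Arrays did not overlap for any of the 23 genes, nor for 15.8% of all genes, where chance gives 10%. With replicate blocks 7 G2/M genes, 3 G1/S genes and 3 chromatin regulators were higher and 3 fibroblast matrix genes lower. The block also gave 1 pluripotency gene, 1 imprinted gene and 1 miR-294 target from other studies higher. Lower were 1 cytokine gene, 1 endothelial marker and 1 miR-181 target from other studies. In the p53 and early lineage lists 1 gene was higher and 1 lower in each. The count was 152 with replicate blocks and 3 on replicates 2 and 3 alone, it was between 0 and 10 with any 1 of the 6 arrays left out, and 0 with these 2 groups fitted alone. It was 15 under median scaling, 46 in the authors' values, 38 on the 12 day 3 arrays without a block and 0 without the 3 arrays with conflicting tags or with groups from the tags.

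Both microRNAs raised 8 genes: Atp12a, Bex4, Cdc20, Dok2, H2ax, the lamin gene Lmnb1, Panx3 and Rbmx. On the 12 day 3 arrays without a block Bex4 had an adjusted p of 0.0582 with miR-181. Independent lists of these sizes would share 0.297 raised genes, and 0 genes were lowered by both. Of the 23 genes changed by miR-181, 22 had the same sign with miR-294, and of the 201 changed by miR-294, 177 had the same sign with miR-181. The 201 genes had a median absolute log2 fold change of 0.70 with miR-294 and a median of 0.26 in the same direction with miR-181. Both comparisons used the same 3 control arrays, which produce likeness by themselves. Of all genes 67.7% had the same sign in both, where simulated groups without effects gave 66.8%. The share for genes called against these controls was not simulated. Across genes the fold changes correlated at 0.516, where simulated groups without effects gave 0.50, and the covariance was 0.0286 against 0.0231 simulated, or 0.0112 with the variance of the fit with replicate blocks. Genes are not independent replicates, and 3 controls do not make 2 parts of at least 2 arrays, so part of the shared genes may come from the controls.

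**Figure D3:**
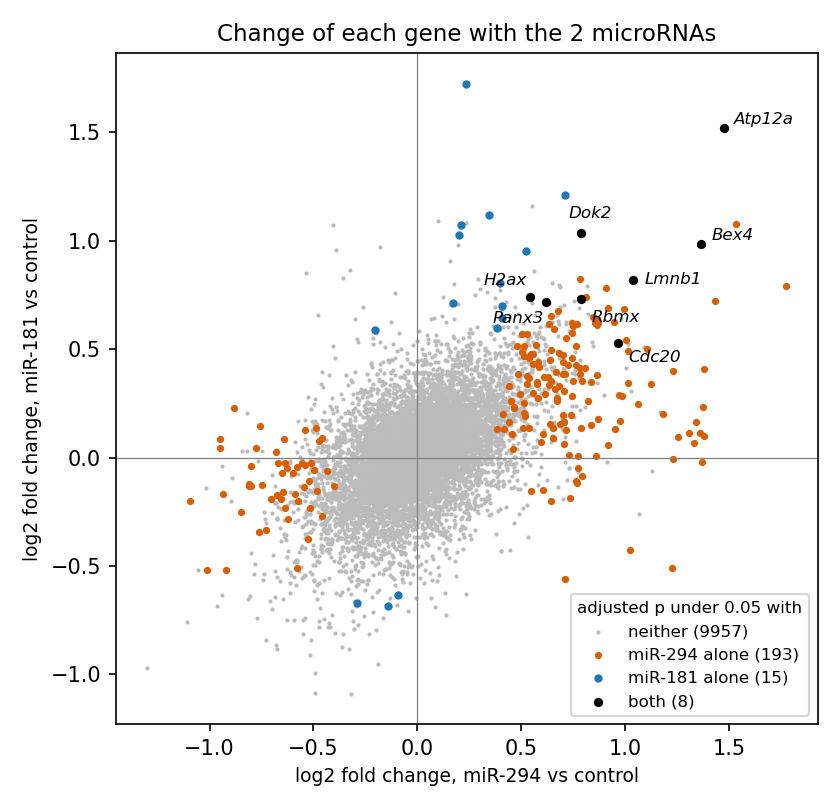
Log2 fold change of each tested gene with miR-294 (horizontal axis) and with miR-181 (vertical axis) against the same 3 OSK control arrays. Points mark genes changed by miR-294 alone, by miR-181 alone, by both (8) or by neither. With the 8 shared genes counted in each, 201 genes changed with miR-294 and 23 with miR-181.

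The direct comparison of the microRNAs found 113 genes, 54 higher with miR-294 and 59 higher with miR-181, and 22 at least 2-fold apart. Higher with miR-294 were the thyrotropin-releasing hormone gene Trh (1.73 ± 0.27, adjusted p = 0.0116), Cpxm1 (1.45 ± 0.16), the adenylyl cyclase Adcy4 (1.39 ± 0.13), the T-type calcium channel Cacna1h (1.32 ± 0.28), Krt8 (1.28 ± 0.25) and Tgfbi (1.27 ± 0.15). Higher with miR-181 were Fbp2 (-1.49 ± 0.19, adjusted p = 0.00436), the proliferin genes Prl2c4 (-1.48 ± 0.24) and Prl2c3 (-1.39 ± 0.24), Clip4 (-1.19 ± 0.24), Ccdc3 (-1.18 ± 0.26) and Akr1c18 (-1.15 ± 0.24). Of the genes changed by miR-294 against the control 54 passed this comparison, and of those changed by miR-181 8 did.

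The G2/M list was higher with miR-294 than with miR-181 at a median of 0.13 with 0 of 20 genes past the test (adjusted p = 0.00639), but its adjusted p was 0.274 with an estimated correlation and 0.0748 by fry. The G1/S list did not pass the camera test (median 0.09, adjusted p = 0.739), and in it E2f1 was lower with miR-294 (-0.63 ± 0.11). Against the control mean, its array medians were 0.33 to 0.45 with miR-294 and 0.24 to 0.28 with miR-181, so a small difference is not excluded. The miR-294 targets were lower with miR-294, at medians of -0.31 for the 12 from other studies and -0.36 for the 6 followed by this study, with adjusted p of 0.019 for each. With an estimated correlation these were 0.219 and 0.274, and by fry 0.00233 and 0.0748. None of their genes passed, and 3 and 2 did adjusted over the list alone, the second list not being independent evidence. Tgfbr2 and Cdkn1a stand in both lists, so the results of the lists are not separate. Tgfbr2 (-1.02 ± 0.25) had an adjusted p of 0.0788, and 0.00197 without and 0.00173 with a block on the 12 day 3 arrays. The miR-181 targets from other studies had a median of 0.13 (adjusted p = 0.144, and 0.0475 without and 0.0375 with a block on the 12 day 3 arrays), and those followed by this study 0.16 (0.329). The endothelial list was higher with miR-294 at a median of 0.18, with Tek (0.77 ± 0.13) the 1 of 11 past the test (adjusted p = 0.04, and 0.219 with an estimated correlation). Its median was 0.0268 with undetected members at their bound.

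Genes higher with miR-294 than with miR-181 in other lists were Dnmt3b (0.85 ± 0.16), the death receptor gene Tnfrsf10b (0.63 ± 0.12), Nras (0.55 ± 0.10), Slc2a3 (1.27 ± 0.21), the neural progenitor gene Nes (0.84 ± 0.14), Laptm5 (1.19 ± 0.23) and Actc1 (1.17 ± 0.22). Genes lower were Epha2 (-0.78 ± 0.13) and Mef2c (-0.73 ± 0.14). Their lists, pluripotency (adjusted p = 0.161), p53 (0.359), Akt (0.63), glycolysis (0.144), early lineage (0.161), macrophage (0.652) and muscle (0.388), did not shift, nor did any of the remaining lists, of which the neural and adipocyte lists had a median, mean and test of differing sign. Under median scaling the pluripotency (adjusted p = 0.0114), early lineage (0.0285) and epithelial lists (0.00856, from 0.161) passed. On the 12 day 3 arrays the fibroblast matrix list had adjusted p-values of 0.0208 without a block and 0.0661 with it, from 0.329. With replicate blocks 476 genes changed, 3 p53 targets were higher and 4 lower, 4 miR-294 targets from other studies and 2 followed by this study were lower and 2 G2/M genes higher. On replicates 2 and 3 alone 15 genes changed, with any 1 of the 6 arrays left out 18 to 48, and with these 2 groups fitted alone 9. The count was 47 under median scaling, 213 in the authors' values, 195 on the 12 day 3 arrays without a block, 3 without the 3 arrays with conflicting tags and 0 with groups from the tags.

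Genes high in iPSC shifted upward by small amounts with both microRNAs. The 200 genes with the highest fold in iPSC over fibroblasts, each at least 9.66-fold, had a median of 0.11 with miR-294 and 0.08 with miR-181. With miR-294 71% of them lay above 0, against 51% of all genes, and 17 rose. With miR-181 66.5% did, against 54.4%, and 2 rose. Camera's adjusted p was 6.39e-07 and 0.00262, and 0.000851 and 0.0151 with an estimated correlation. Under median scaling the miR-181 shift did not pass (adjusted p = 0.251), at a median of 0.11 where that of all genes was 0.104. In the miR-294 comparison 64 of the 200 genes were undetected in both groups and 22 in 1 of them, and with such genes set at 0 or at their bound the median was 0 for either microRNA. The 200 genes highest in fibroblasts, each at least 8.88-fold, had medians of -0.14 and -0.06, the latter 0.03 under median scaling, with adjusted p of 0.000188 and 0.0041, but 0.603 for each with an estimated correlation. Of these, 0 passed with miR-294 and 2 rose with miR-181.

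**Figure D4:**
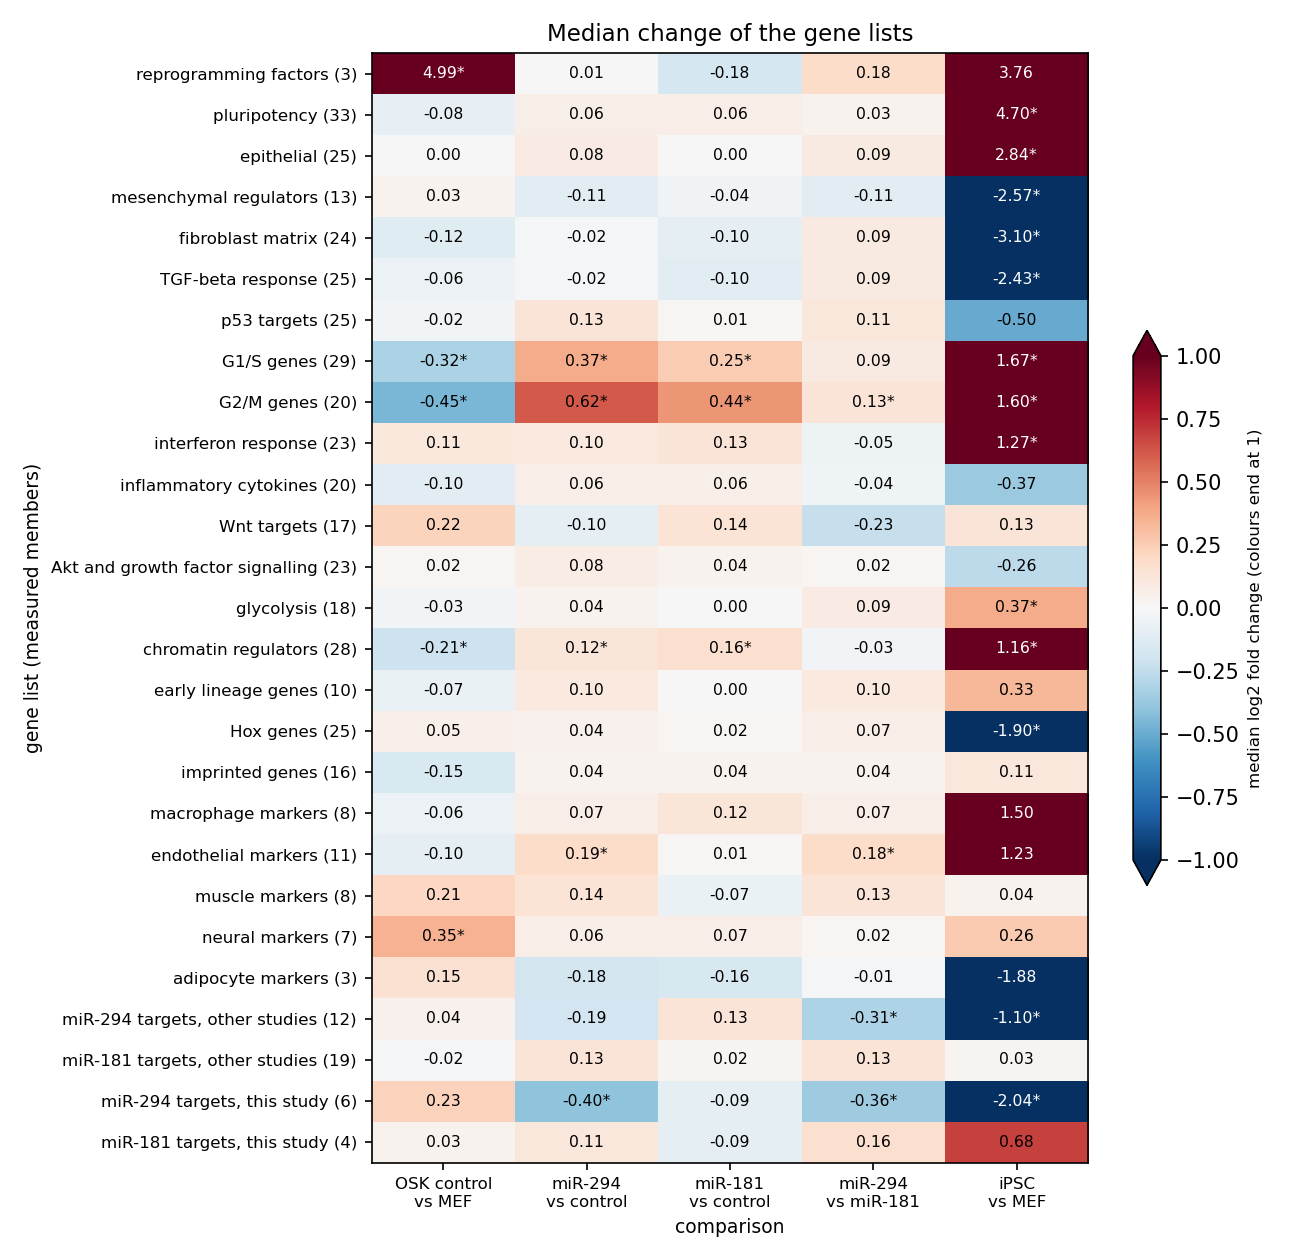
Median log2 fold change of the 27 gene lists (vertical axis, measured members in brackets) in the 5 comparisons (horizontal axis), with an asterisk where camera's adjusted p passed 0.05. The G2/M list had medians of -0.45, 0.62, 0.44, 0.13 and 1.60.

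iPSC lines and fibroblasts, the end points of reprogramming, differed in 6585 of 10173 genes, 3388 higher in iPSC and 3197 lower, and in 3837 at least 2-fold. Pluripotency genes were the most raised, 31 of 33, at a median of 4.70 or, with undetected members at their bound, 4.39. Dppa5a rose by 9.77 ± 0.20 (adjusted p = 2.71e-13) and Pou5f1 by 7.44 ± 0.36. Dnmt3l, a cofactor of DNA methylation, was at least 535-fold higher, Dppa4 at least 327-fold, Sall4 at least 122-fold and Utf1 at least 86.1-fold. Sox2 was at least 9.50-fold higher, and Klf4 stood at 0.39 ± 0.30 (adjusted p = 0.284). For the 3 factors camera's adjusted p was 0.0573, 0.0421 and 0.0472 with these 6 arrays alone, without and with a block, and 0.0247 under median scaling. Outside the lists the oocyte gene Ooep and Trh were at least 153-fold and 158-fold higher.

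Epithelial genes rose as a list, 21 of 25 with 2 lower, at a median of 2.84 or 2.44 with undetected members at their bound, among them the claudin gene Cldn6 (6.82 ± 0.21), Grhl2 (at least 13.4-fold) and Rab25 (at least 13.2-fold). Among the lowest fold changes in iPSC were Igfbp5 (-8.05 ± 0.19, adjusted p = 1.03e-12), the surface antigen gene Thy1 (-6.24 ± 0.21), the adhesion receptor gene Vcam1 (-6.09 ± 0.44), Chst2 (-5.84 ± 0.17) and C1qtnf3 (-5.74 ± 0.28). Of 24 fibroblast matrix genes 22 fell, at a median of -3.10, such as the protease gene Mmp14 (-3.46 ± 0.19). Of 13 mesenchymal regulators 11 fell, such as Twist1 (-2.54 ± 0.15), Zeb2 (-2.79 ± 0.19) and Prrx1 (-4.93 ± 0.31), and of 25 TGF-beta response genes 22, with 1 higher, such as Tgfbr2 (-3.58 ± 0.25) and Tpm1 (-2.35 ± 0.16). Camera's adjusted p was 7.14e-07 for the epithelial list, 4.4e-08 for fibroblast matrix, 6.7e-05 for mesenchymal regulators and 3.99e-06 for the TGF-beta response. With an estimated correlation these were 0.00902, 0.178, 0.0965 and 0.185.

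Cell-cycle genes were higher in iPSC, 19 of 20 G2/M genes at a median of 1.60 and 23 of 29 G1/S genes at 1.67, where 2 were lower, with Ung (3.70 ± 0.10), Mcm5 (2.86 ± 0.13), Bub1b (2.51 ± 0.13) and Cdc20 (2.24 ± 0.10) among them (adjusted p = 1.13e-06 and 3.99e-06, and 0.0367 and 0.00902 with an estimated correlation). Cdkn1a changed by -2.22 ± 0.12. Chromatin regulators rose, 19 of 28 with 3 lower, such as Dnmt3b (7.34 ± 0.16), Parp1 (2.51 ± 0.11) and the Polycomb gene Suz12 (1.42 ± 0.09), at an adjusted p of 0.000836, or 0.0146 with an estimated correlation. Hox genes fell, 21 of 25 at a median of -1.90 or -1.55 with undetected members at their bound, with Hoxc9 at -4.80 ± 0.32 and Hoxc10 at least 13.0-fold lower (adjusted p = 5.12e-06, and 0.045 with an estimated correlation). Interferon response genes rose as a list, 16 of 23 with 2 lower, such as Ifitm3 (1.42 ± 0.09), and so did glycolysis genes, 10 of 18 with 2 lower, such as Slc2a3 (6.33 ± 0.21), Pdk1 (3.77 ± 0.18) and Hk2 (1.76 ± 0.10). Their adjusted p-values were 0.0157 and 0.0276, and 0.224 and 0.207 with an estimated correlation.

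Targets of miR-294 were lower in iPSC, 7 of 12 from other studies with 1 higher, such as Irf2 (-2.85 ± 0.18), and 4 of 6 followed by this study, such as Dpysl2 (-2.10 ± 0.11) and Cfl2 (-1.97 ± 0.20), the second list not being independent evidence. Camera's adjusted p-values were 0.0276 and 0.0105, and 0.0965 and 0.178 with an estimated correlation. Both lists hold Tgfbr2 and Cdkn1a, so their results are not separate. Targets of miR-181 did not shift (8 of 19 higher and 5 lower, adjusted p = 0.49; 2 of 4 higher and 1 lower, 0.688). The p53 (7 higher and 13 lower of 25, 0.0746), cytokine (3 and 8 of 20, 0.356), Wnt (6 and 7 of 17, 0.896) and Akt lists (7 and 10 of 23, 0.276) held members of both directions, as did the early lineage (5 and 2 of 10, 0.503) and imprinted lists (6 and 5 of 16, 0.969), with Phlda2 at 6.00 ± 0.22 and Igf2 at -2.08 ± 0.14. Among other cell types, macrophage markers had 5 of 8 higher (0.0893, and 0.0361 under median scaling), endothelial markers 7 of 11 higher and 3 lower (0.115), muscle markers 3 and 3 of 8 (0.896), neural markers 2 and 2 of 7 (0.969) and adipocyte markers 2 of 3 lower (0.2). Fry called the 13 lists that shifted and also the factors, p53, Akt, early lineage, macrophage, endothelial, adipocyte and both miR-181 target lists. The Wnt, muscle and neural lists had a median, mean and test of differing sign. Laptm5 stood at 5.59 ± 0.23 and Lyz2 at 4.13 ± 0.68.

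Arrays did not overlap for 6321 of the 6585 genes, where 66.1% of all genes did not overlap and chance gives 10%. With replicate blocks 6579 genes changed, 6214 of them the same genes, and on replicates 2 and 3 alone 6612.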

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

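The criteria for a lone sample, for opposite effects in parallel groups and for signal in unused data could not be applied to this design. A lone sample needs at least 4 samples in a group, no comparison was repeated in parallel groups, and every sample was used. Instead, 3 patterns were chosen for their bearing on the comparisons. The tests of the virus stock, of a single control array, of the share of factor-expressing cells, of transfection and of the tag on the fibroblast array were chosen after the result was seen. The wording of 2 explanations for replicate 1 was narrowed after their result, with the bounds left as written.

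The replicate 1 arrays lay apart from replicates 2 and 3 in every group. The uninfected fibroblast array shared the deviation of the infected replicate 1 arrays at a correlation of at least 0.572, which argues against the virus stock, and the iPSC array of replicate 1 shared it at 0.492 to 0.505. Of 237 genes whose tested probe read at least 1 log2 unit lower in replicate 1 (5 read higher), 23 had another probe detected on all arrays, and while the tested probes had a median deviation of -1.25, these other probes had one of -0.0233 (quartiles -0.46 to 0.20). The ratio of both medians was 0.0186. For most of these 23 genes the tested probe read low by itself, as for Esd (-2.21 and 0.04) and Pabpc1 (-1.97 and 0.31), which argues against lower transcript levels there. The tested probes were picked for a low reading, and other probes that fell below detection in replicate 1 were left out. Both steps lower the ratio, so it does not decide the question for the 237 genes as a whole. In 5 of the 23 genes, Ctnnb1 and Smad1 among them, the other probes shared at least 50% of the deviation. Lower transcript levels stay open for these 5 and for the genes without another probe detected on all arrays. The fibroblast preparation stays open for all 237 genes, since other probes of a gene bear on its transcript level and not on the preparation. The labels do not say which preparation the iPSC line came from. Median raw signal also differed by number in every group, and array processing and RNA integrity were not tested.

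Cell-cycle genes were lower in OSK control cultures than in fibroblasts and higher with either microRNA than in the control. The values argue against a single control array as the source, since without any 1 of them the G2/M median was 0.571 to 0.658 with miR-294 and 0.420 to 0.473 with miR-181. Fewer factor-expressing cells in the microRNA cultures would lower the 200 genes most raised by OSK infection, at a median of 1.84, but these had medians of -0.0297 with miR-294 (quartiles -0.28 to 0.23) and 0.0366 with miR-181 (quartiles -0.13 to 0.24), while the 3 factors lay at -0.81 to -0.04 with miR-181, so a small loss there is left open. Transfection of any small RNA stays open, since the labels do not say whether controls were transfected and the microRNAs differed by 0.132 in the G2/M median. An effect of the microRNAs on proliferation is the biological explanation that the design offers, and cannot be told apart from transfection here.

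The treatment tags of 3 replicate 2 samples disagree with their titles. The tagged fibroblast array carried the 3 factor transcripts at a position of -0.114 on a scale from the other fibroblasts (0) to the infected arrays (1), against its having been infected. On 100 genes that separate the microRNAs in replicates 1 and 3, the array titled miR-294 lay at 0.905 between miR-181 (0) and miR-294 (1). On another 100 genes, which separate miR-181 from the control there, the array titled miR-181 lay at 0.717 between control (0) and miR-181 (1). Both positions go against the tags, and both were taken relative to the OSK control array of replicate 2. The results under the tag grouping, 1, 0 and 0 genes for the microRNA comparisons, had been seen when these tests were written. Grouping by title was kept, and a swap with a sample outside these groups was not tested.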

How the results depend on the processing

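The alternatives with replicates 2 and 3 alone and with a replicate block over all 15 arrays were added after the data were seen. The count for iPSC against fibroblasts stayed within 1.5 times of 6585 under every alternative except the 2-fold minimum, which left 3837. Leaving out 1 array gave 6185 to 6447. None of 182 named gene results changed sign under any alternative that could be fitted. Of the 175 past the threshold, 11 lost it in the authors' values, 35 under median scaling, 21 with the mean of a gene's probes, 52 with 2 groups alone, 67 on replicates 2 and 3 alone, 88 with groups from the tags and 74 without the 3 arrays with conflicting tags. Of 121 at day 3, 2 lost it on the 12 arrays without a block, Ptx3 with miR-294 and Bex4 with miR-181, and 0 with the planned replicate block. Leaving out a miR-294 array lost 28 to 33 of 57, a miR-181 array 23 to 28 of 38 and an OSK control array 27 to 48 of 98. In the other comparisons a 2-fold minimum left 314 genes for OSK infection, 28 for miR-294, 7 for miR-181 and 22 for the direct comparison. Background correction with offset 50 gave 36 genes for miR-181 and 176 for the direct comparison, and the authors' values gave 339 for miR-294, 46 for miR-181 and 213 for the direct comparison. Median scaling gave 72, 15 and 47, and put the median of all genes at 0.104 for miR-181 against the control, where it was 0.0185. Under it the genes higher and lower were 430 and 442 for OSK infection, 62 and 10 for miR-294, 15 and 0 for miR-181, 15 and 32 for the direct comparison, and 2831 and 3430 for iPSC. For miR-181 the stricter detection filter gave 39 genes, every probe by itself 13, the mean of a gene's probes 14, and trend with robust estimation 42. Array weights gave 2131 for OSK infection and 876, 137 and 362. The 2 groups compared alone gave 84, 0 and 9. For miR-181 limma's unadjusted p was under 0.05 for 831 genes with all arrays, and the causes of these shifts were not tested, except where fewer arrays were fitted.

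With the replicate number as a block over the 12 day 3 arrays, 2088, 713, 152 and 476 genes changed, where the same 12 arrays without a block gave 1361, 327, 38 and 195. Over 15 arrays the block gave 1532, 395, 69 and 232. A block takes deviations shared by a number out of the error. List calls on the 12 arrays were the same without and with the block, except for the neural list after OSK infection (adjusted p = 0.0631 and 0.0224) and the fibroblast matrix list in the direct comparison. Calls that differed from those with all arrays stand beside their results. With the block over 15 arrays the endothelial list had 0.054 with miR-294 and 0.0903 in the direct comparison, the miR-294 targets from other studies passed with miR-294 (0.0169), and no other list's call changed. On replicates 2 and 3 alone the counts were 31, 3 and 15 for the microRNA comparisons, groups from the treatment tags gave 1, 0 and 0, and without the 3 arrays with conflicting tags 602, 16, 0 and 3 genes changed, with fewer arrays per group. Leaving out 1 array at a time gave 665 to 765 for OSK infection, lowest without OSK control 3. For miR-294 the counts were 102, 58 and 33 without OSK control 1, 2 and 3 and 76, 58 and 78 without miR-294 arrays 1, 2 and 3. For miR-181 they were 10, 2 and 0 without those controls and 2, 6 and 5 without miR-181 arrays 1, 2 and 3. For the direct comparison they were 38, 33 and 18 without miR-294 arrays and 44, 27 and 48 without miR-181 arrays. A group left with fewer arrays was assumed to vary like the others.

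The miR-294 targets from other studies had medians of -0.24 to -0.16 in every alternative. Their adjusted p of 0.0734 passed by fry (0.00536), with the block over 15 arrays, and in 7 further alternatives: the authors' values (-0.17, p = 0.0318), no detection filter (-0.16, 0.0331), the mean of a gene's probes (-0.21, 0.0426), the 12 arrays without (-0.19, 0.0311) and with the block (-0.19, 0.00676), replicates 2 and 3 alone (-0.18, 0.025) and without miR-294 array 2 (-0.24, 0.047). With 1 array left out their median was -0.24 to -0.18 at adjusted p of 0.047 to 0.158. The direction of the miR-181 targets turned up without OSK control 2 (0.0695) and without miR-181 array 1 (0.04), in a leave-one-out range of 0.00207 to 0.0695, and did not pass. The iPSC-high set with miR-181 lost its call under median scaling (0.11, adjusted p = 0.251). The fibroblast-high sets lost theirs with an estimated correlation (-0.143 and -0.0645, 0.603), and the miR-181 one without miR-181 array 1 (-0.0719, 0.0815, in a range of -0.0981 to -0.0586). The correlation of fold changes was 0.385 to 0.630 with 1 array left out, 0.630 without OSK control 1, 0.416 without miR-294 array 2 and 0.385 without miR-181 array 1. With an estimated correlation 3, 0 and 6 lists shifted for miR-294, the direct comparison and iPSC, fry called 11 for OSK infection and 9, 2 and 22 for these, and the block 5 for miR-181. The causes were not tested. Genes near background are the limit of the signal: between 46.6% and 52.1% of probes were detected on an array, and folds against undetected groups are lower bounds.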

Other observations

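The tests in this part were written before their values were seen, with the shift of the iPSC-high set already known. iPSC lines differed from fibroblasts in further genes of known function. Tfap2c, a transcription factor of germ cell precursors and trophoblast, was at least 57.1-fold higher and the Polycomb gene Cbx7 at least 27.8-fold. Icam1 rose by 3.54 ± 0.16 and the deacetylase gene Sirt1 by 2.57 ± 0.13, while Wnt5a (-4.53 ± 0.31), Igf1r (-2.61 ± 0.25) and the survival gene Bcl2 (-2.85 ± 0.14) fell. Genes of contractile tissue went both ways, with the troponin gene Tnnt1 at least 16.7-fold higher and the actin gene Acta1 at -4.04 ± 0.29. Of the sex-linked genes 2 were measured: Xist, the transcript of X inactivation, was at least 4.30-fold lower in iPSC and was detected on all 12 day 3 arrays, and Uty lay near background in all groups.

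Of 878 detected probes without a gene name, 67 passed the threshold for OSK infection, 7 for miR-294, 0 for miR-181, 4 in the direct comparison and 519 in iPSC, in the limma fit of every probe by itself. Array 3 of miR-181 lay nearest to the control, at 0.365 between control (0) and miR-181 (1) on the 100 genes that separate these groups in the other replicates, where arrays 1 and 2 lay at 0.729 and 0.717.

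A hypothesis was that each microRNA moves OSK-infected cells toward the iPSC profile outside the cell cycle. Of 185 genes changed by miR-294 and not on the cell-cycle lists, 143 (77.3%) had a fold change of the same sign between iPSC and fibroblasts. They were 106 of 136 raised and 37 of 49 lowered genes, and 132 of them passed the threshold there. By chance 49.8% would, taking the 49.5% of all genes that were higher in iPSC. The share of the changed genes that were higher in iPSC would put chance above 49.8%. No array is shared between these comparisons, and the value goes with the hypothesis, but proliferation genes outside the lists and transfection of any small RNA may account for part of it. On the first principal component the miR-294 arrays lay at -27.2 to -26.4 and the miR-181 arrays at -31.6 to -29.1. OSK control arrays lay at -35.5 to -33.3, fibroblasts at -24.3 to -23.1 and iPSC at 108 to 124. On this axis the arrays given a microRNA were thus nearer to iPSC than the control was, but no nearer than uninfected fibroblasts. For miR-181 it was 13 of 22 genes (59.1%, 11 past the threshold, against 49.6% by chance from all genes), too few to decide. These were 12 of 19 raised and 1 of 3 lowered genes. The changed genes' own share would put chance higher here too, so 59.1% need not lie above it.

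Other splits of the 6 arrays of each comparison into groups of 3 were fitted, 10 with the real one, which are too few for a share under 0.05. In each comparison 1 split, the real one, gave as many genes as observed. The real splits gave 1006, 201, 23, 113 and 6585 genes for OSK infection, miR-294, miR-181, the direct comparison and iPSC, and the highest of the others gave 0 in each. Like the real split, 3 of the others part all 3 pairs of equal numbers and gave 0. The remaining 6 keep replicate numbers together on a side and part 1 pair. Every split other than the real one mixes the 2 groups, which puts their difference into the error. Low counts were therefore likely beforehand and add no support.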
